A study of Drosophila melanogaster with 54 samples.

How the data were processed

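Polysome profiles and ribosome footprints of Drosophila melanogaster were measured in mature (stage 14) oocytes and in activated, unfertilised eggs collected over 2 h. Per the labels' protocols, a lysate was separated on a sucrose gradient and collected as 6 fractions: free RNA-protein particles (RNPs), 40S, 60S with 80S, low polysomes (2 to 4 ribosomes), medium polysomes (5 to 9) and heavy polysomes (10 or more). An unfractionated part of the lysate, called the input, was sequenced beside them. Each stage had 2 replicate gradients and 1 gradient of a lysate treated with 2 mM puromycin, a drug that releases elongating ribosomes. Per the labels' protocols, puromycin lysates were also made and run in other buffers than the rest, without cycloheximide, so drug and buffer cannot be told apart. The second set of 12 libraries held ribosome-protected fragments and RNA of oocytes, eggs and eggs of png mutant mothers, each with and without cycloheximide, a drug that stalls ribosomes. Libraries were made from poly(A)-selected RNA, per the labels' protocols. Altogether 54 samples were used, 42 with a table of their own.

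Input tables held RPKM values, per the file headers, for 14250 genes. Fraction tables held RPKM values normalized by the authors, per the file headers, and beside each the fraction of the gene's mRNA in that part of the gradient, deposited as a number from 0 to 1. That fraction equalled the RPKM value divided by the gene's sum over the 6 parts of the gradient, within 0.0052. Per the series design, 5 ng of yeast mRNA was added to each fraction so that levels could be compared across a gradient. How the authors' normalization used it is not given in the sources used here. The spiking was not the same throughout. For oocyte replicate 1 alone the labels give a number of spiked gradient fractions, 14. A further 5 ng luciferase spike-in is given for the egg gradients and both puromycin gradients, but not for the oocyte gradients without puromycin. Whether this affected the scaling was not tested. The footprint table held RPKM values of 5842 transcripts, per the file headers, without a spike-in. TopHat 1.3.2, Bowtie, HTSeq, FastQC and the genome build dm3 were named in the submitters' processing notes without their roles. No values were in read counts, so the depth per sample is unknown and no counting interval was computed. Each gradient table listed only genes with a heavy-polysome value of at least 4 in that gradient, as tested on the values; genes that left the heavy polysomes altogether were therefore missing from the comparison. Gene names were taken from the tables and matched to gene records of the assembly Release 6 plus ISO1 MT by name, synonym or accession, for names only, and transcript and coding lengths came from an Ensembl annotation of BDGP6. Of 14258 names 13567 (95.2%) matched, as did 5784 of the 5842 transcripts, while 5 names that read as dates did not.

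The polysomal share of a gene was its amount in medium and heavy polysomes over its amount in all 6 fractions, and was tested as log2 odds against the other 4 fractions with 1 added to each side. Translational efficiency was log2(footprint RPKM + 1) minus log2(RNA RPKM + 1). Tests used limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p-value below comes from limma unless another test is named. Changes are called higher, lower, risen or fallen where they passed that threshold. The plan fixed before the data were examined set a count model for count tables and limma for other units, and limma was used throughout. Inputs were compared between 2 oocyte and 2 egg libraries. A single model over all 6 gradients gave the polysomal comparisons, with the lone puromycin gradient of a stage assumed to vary as the replicates did. A single model over the 12 footprint-series libraries gave translational efficiency and RNA comparisons, with a cycloheximide term for each assay, so that the states with and without cycloheximide served as 2 observations per stage. These p-values measure only the spread between these few samples. In the footprint series that spread is the part of the cycloheximide effect that differed between stages or genotypes. No stage or genotype was repeated within a cycloheximide state, so variation between biological samples was not measured. Footprint and RNA libraries of the same sample entered the model as independent. Filters were a mean of 1 RPKM for inputs and footprints and a mean sum of 10 over the fractions. They were set after the tables were opened and before any test, and the filter on gradients removed no gene, leaving 5088 genes listed in all 6 gradients. Summaries and exact tests used python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and, for plots, matplotlib 3.10.9.

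Genes named below were chosen by a rule written before the data were examined. It takes, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold that moved the same way in every replicate or cycloheximide state and lay above the lower quartile of mean level. It also takes 29 genes fixed beforehand and the 4 members with the smallest p of each gene list. The 29 genes (for example png, smg, CycB, osk and Tl) are called regulators below. They include genes of egg activation, the cell cycle and axis patterning. Genes known only by a CG number were left unnamed where possible, and where a list of names was shortened, the number left out is given by the counts. Gene lists, also written beforehand, covered cell cycle and meiosis regulators, egg activation and calcium signalling, maternal axis patterning, post-transcriptional regulators of maternal mRNA, early zygotic activators, follicle cell (chorion and vitelline membrane) genes, yolk genes, other somatic cell genes, cytosolic and mitochondrial ribosomal proteins, the proteasome, translation factors, the respiratory chain, DNA replication, and histones with chromatin of the early embryo. Lists with at least 5 members were tested with camera at a preset correlation of 0.01 and again with an estimated one. Of 133 list tests 43 passed with the preset correlation and 1 with the estimated correlation, the follicle cell list in the inputs. The result of 1 of the genes that the rule picked is not reported here.

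Alternatives were the pseudocount (0.1 and 5), no filter and a filter 4 times stricter, other definitions of polysomal, scaling of each fraction to its own total, centring on the median gene, each library left out in turn, the replicate number as a block, and only the libraries compared. Footprint to RNA ratios per sample, the replicate block with centring, and the difference of the puromycin effect between stages were added after the data were seen, as was the share of all mRNA without the follicle cell list or over genes listed in every gradient. Count-based normalizations were not run on RPKM values. The models were tested on simulated data with 200 changed genes per comparison. At a log2 change of 1 they recovered 82% of changed genes for the polysomal share, 59% for inputs, 53% and 71% for puromycin in oocytes and eggs, and 46% and 47% for translational efficiency of eggs and of png eggs; at 2, at least 98%. False calls numbered 5 to 15.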

Results

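Polysome gradients followed the mRNA of mature Drosophila oocytes and of activated eggs, 2 replicate gradients of 6 fractions each and 1 puromycin gradient per stage, with the 6 unfractionated inputs. Ribosome footprints and RNA came from oocytes, eggs and png mutant eggs, 1 library per assay without and 1 with cycloheximide. The eggs were laid by females mated to spermless males, so activation took place without fertilisation. Between 5563 and 6297 genes were listed per gradient, 14250 per input, all in RPKM, and 5840 transcripts with footprints and RNA were tested, and read depth is unknown. Single-gene values from gradients and inputs are means ± SD over the 2 replicates of a stage, those of translational efficiency over 1 library pair without and 1 with cycloheximide, and puromycin values come from 1 gradient.

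How much mRNA sat on polysomes before and after activation was read from the gradient totals. In oocytes 35.2% ± 2.0 (SD, n = 2) of the mRNA of the listed genes was in medium and heavy polysomes, and in eggs 22.8% ± 2.1 (SD, n = 2). The difference was larger than the spread between replicates, whose values were 36.6% and 33.8% in oocytes and 24.2% and 21.3% in eggs. Free particles held 15.8% ± 1.2 in oocytes and 31.0% ± 1.8 in eggs (SD, n = 2). After puromycin the polysomal part was 17.5% in oocytes and 8.8% in eggs, with no replicate. Follicle cell mRNA took part in the oocyte totals: Cp15 alone made up 19.49% and 25.66% of the medium polysome values in oocytes. With the follicle cell list left out, a choice made after the data were seen, the polysomal part was 33.3% and 29.2% in oocytes and 24.2% and 21.3% in eggs. Over the 5088 genes listed in every gradient the values were 33.1% and 29.0% in oocytes, 24.1% and 21.3% in eggs, and 18.0% and 8.8% after puromycin. No test was run on these totals, which rest on the authors' scaling of fractions. That scaling was not checked here, and below it decided the median change per gene. The spike-ins also differed between the oocyte gradients without puromycin and all other gradients, as given above.

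**Figure D1:**
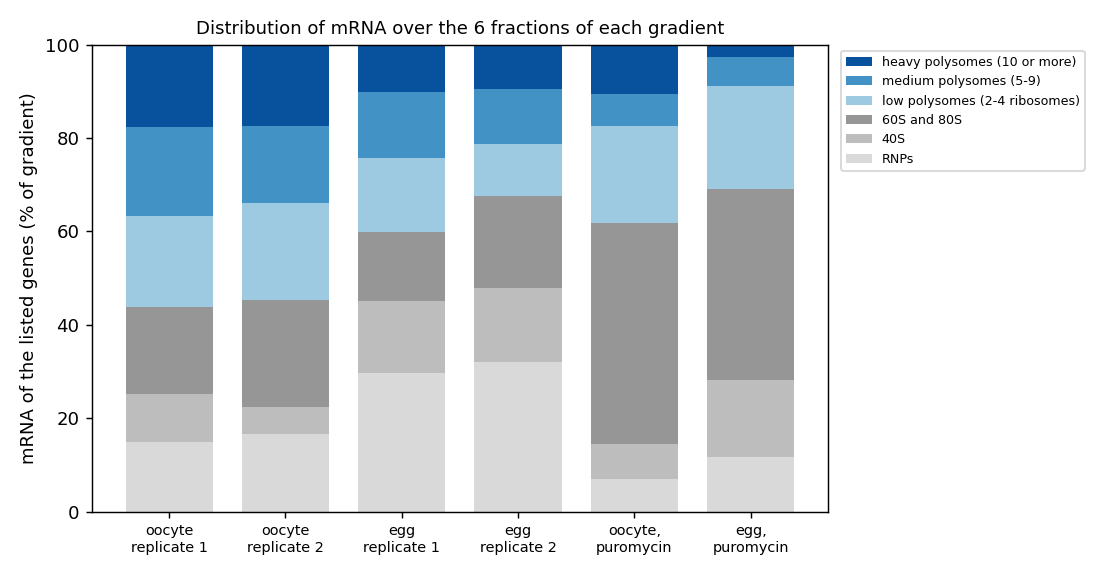
Stacked bars give the share (%) of the mRNA of the listed genes in each of the 6 sucrose fractions of each of the 6 gradients. Medium and heavy polysomes together held 36.6% and 33.8% in oocytes, 24.2% and 21.3% in eggs, and 17.5% and 8.8% in the puromycin gradients of oocytes and eggs.

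Which mRNAs moved onto or off polysomes at activation was tested on the share of each gene's mRNA in medium and heavy polysomes. The mRNA of eIF4AIII, an RNA helicase of the exon junction complex, rose from 27.6% ± 2.69 in oocytes to 79.2% ± 2.29 in eggs (SD, n = 2; limma adjusted p = 0.000115). The mRNA of kin17, a nuclear DNA- and RNA-binding protein, rose from 29.3% ± 1.05 to 80.2% ± 1.34 (SD, n = 2; log2 odds 3.27 ± 0.20 SE), that of the deglycosylating enzyme PNGase from 21.9% ± 1.32 to 70.8% ± 1.0, and that of the immune signalling gene key from 31.5% ± 2.66 to 79.0% ± 0.9. Among mRNAs that fell, that of the malic enzyme Men went from 67.6% ± 4.18 to 8.63% ± 1.71 (SD, n = 2; log2 odds -4.44 ± 0.22 SE, adjusted p = 0.000115). The helicase gene RecQ4 fell from 69.7% to 9.23%, the small heat shock gene Hsp27 from 81.1% to 19.8%, the peroxidase gene pxt from 78.4% to 18.6%, and the glycolytic gene Gapdh2 from 56.8% to 9.21%. The mRNA of mtrm, which encodes an inhibitor of Polo kinase in oocyte meiosis, fell from 72.4% ± 2.38 to 12.5% ± 0.902 (SD, n = 2).

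Of 5088 genes tested with limma 3517 passed the threshold, 924 higher and 2593 lower in eggs, with a median log2 odds change of -0.60 over all genes. That balance rests on the authors' scaling of fractions. With each fraction scaled to its own total the median was 0.07 and 1807 genes were higher and 1522 lower, and with gradients centred on their median, which brings it near 0 by construction, it was -0.09 with 1594 higher and 1883 lower. All 924 genes called higher were called higher under both, whereas of the 2593 called lower 1521 and 1883 were. Both scalings moved the median up, which favours keeping higher calls, so this does not show the rises to be firmer than the falls.

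Among cell cycle genes, of which 9 of 35 were higher and 15 lower, CycA, a mitotic cyclin gene, rose from 32.5% ± 1.59 to 64.6% ± 5.47 of its mRNA in medium and heavy polysomes (SD, n = 2; log2 odds 1.93 ± 0.22 SE, adjusted p = 0.000461), and CycB from 33.7% ± 0.179 to 52.2% ± 9.5. The gene for the anaphase-promoting complex activator fzy rose from 56.6% ± 4.79 to 74.1% ± 5.68 (log2 odds 1.14), a call lost without oocyte replicate 2 (log2 odds 0.94, adjusted p = 0.0999). The receptor genes tor and Tl, which pattern the termini and the back-belly axis, rose from 29.3% ± 0.0961 to 54.4% ± 5.32 and from 29.5% ± 0.874 to 37.6% ± 4.55. The Tl call was lost when either oocyte gradient or egg replicate 1 was left out, with log2 odds of 0.47, 0.56 and 0.32. With low polysomes included 4 of the regulators named beforehand lost their call. CycB, fzy and Tl were among them, at log2 odds of 0.36, 0.55 and 0.25. The Tl call was also lost with a pseudocount of 5 (0.49, limma adjusted p = 0.0514).

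Among the regulators named beforehand, the kinase gene png, which triggers translation at egg activation, fell from 34.9% ± 3.49 to 11.7% ± 0.504 (SD, n = 2; log2 odds -2.01 ± 0.18 SE, adjusted p = 0.000187), and its partner gene gnu fell from 47.6% to 20.5%. The meiotic anaphase-promoting complex activator cort fell from 46.4% ± 6.3 to 10.4% ± 0.438 (SD, n = 2) and the cytoplasmic poly(A) polymerase gene wisp from 39.8% ± 2.05 to 8.81% ± 0.489. The mRNAs of the repressor proteins tral, cup, me31B and pum fell from 64.5% to 15.1%, 53.6% to 12.4%, 50.2% to 20.1% and 50.2% to 16.9%. Among patterning mRNAs, of which tor and Tl rose, nos fell from 19.3% to 5.43%, osk from 46.3% to 20.9%, hb from 40.0% to 15.5% and zld, listed as vfl, from 50.9% to 35.8%, where the zld call ended with centred gradients (log2 odds -0.38, adjusted p = 0.13). The mRNA of bcd fell from 71.0% ± 4.38 to 52.4% ± 9.76 (log2 odds -1.12), a call lost without oocyte replicate 1 (-0.90), oocyte replicate 2 (-1.35) or egg replicate 2 (-0.73), and with either other scaling (-0.66 and -0.61). The thioredoxin gene dhd, whose protein remodels sperm chromatin, fell from 67.3% ± 5.96 to 14.2% ± 1.88 (SD, n = 2).

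Of the 29 regulators named beforehand 5 were higher, 14 lower and 10 not called. Those not called were plu, smg, CycB3, stg, twe, polo, sra, cad, brat and BigH1 (listed as CG3509), with log2 odds from -0.45 for twe to 0.43 for CycB3. The mRNA of smg, a repressor that brings about maternal mRNA decay, stood at 40.1% ± 1.09 and 45.9% ± 7.49 (SD, n = 2; adjusted p = 0.256). With egg replicate 2 left out, smg (0.65), CycB3 (0.78), twe (-0.70) and plu (-1.07) were called, and plu turned to 0.61 without egg replicate 1. With each fraction scaled to its own total, polo (0.52), cad (0.54), smg (0.84), CycB3 (0.95), sra (0.83) and CG3509 (1.17) were called higher, the last 4 also with centred gradients. With low polysomes included, polo (-0.93), cad (-1.09), stg (-0.79), twe (-0.72) and brat (-0.72) were called lower, and in heavy polysomes alone twe was (-1.21).

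Among gene lists, the direction was shared by all 3 scalings for only some. Of 34 post-transcriptional regulators 23 were lower and 4 higher, the same counts as adjusted over the list alone, with a median 0.98 below that of all genes; larp fell from 46.4% to 10.1%. Of 35 DNA replication genes 23 were lower and 6 higher, likewise adjusted over the list alone, led by the DNA polymerase gene DNApol-delta (48.0% to 7.76%) and the nuclease gene Fen1 (40.3% to 6.07%). Of 21 histone and chromatin genes 14 were lower (13 adjusted over the list alone) and 0 higher. Of 26 axis genes 15 were lower and 7 higher, including dl with 54.2% in oocytes and 12.8% in eggs, and of 8 activation genes 6 were lower, including CanB2 with 32.6% and 19.2%, which was not called with each fraction scaled to its own total (log2 odds -0.22). These lists kept more genes lower than higher under each scaling. Of 83 cytosolic ribosomal protein genes 64 were lower and 1 higher (65 and 1 adjusted over the list alone; camera adjusted p = 0.037, and 0.975 with an estimated correlation), RpL38 among them though not in heavy polysomes alone (log2 odds -0.42), but with each fraction scaled to its own total 10 were higher and 1 lower. The proteasome (16 lower and 5 higher of 31, Rpn2 among the lower), mitochondrial ribosomal protein (29 and 8 of 71), translation factor (20 and 2 of 39) and cell cycle lists (15 and 9 of 35, nod among the lower) were likewise lower as deposited but had 15, 28, 18 and 15 genes higher against 9, 6, 5 and 12 lower with each fraction scaled to its own total. Adjusted over the list alone, these 4 lists had 15 and 5, 28 and 8, 18 and 1, and 16 and 9 genes lower and higher. Of 63 respiratory chain genes 24 were lower and 5 higher (16 and 0 adjusted over the list alone), and of 6 early zygotic genes 3 were lower and 1 higher, which became 3 and 3 with that scaling. No list besides the cytosolic ribosomal proteins passed camera here. The yolk receptor gene yl and the somatic gene Tm1 were the only tested members of their lists.

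Whether mRNA levels changed was tested on the inputs. As libraries came from poly(A)-selected RNA, a change in poly(A) tails cannot be told apart from a change in amount. Follicle cell mRNAs, which encode eggshell proteins made by the cells around the oocyte, were abundant in oocyte inputs and nearly missing from egg inputs. The mRNA of Cp18 was at 1570 ± 214 RPKM in oocytes and 0.222 ± 0.0395 RPKM in eggs (SD, n = 2; log2 -10.32 ± 0.26 SE, adjusted p = 3.13e-09). Cp15 had 25160 and 19170 RPKM in oocytes and was listed at 0 in egg replicate 1 and at 0.1224 RPKM in egg replicate 2, Cp19 had 539 ± 55.2 RPKM in oocytes and 0 and 0.09674 RPKM in eggs, and Cp16 had 467 ± 61.3 RPKM and was listed at 0 in both eggs. All 20 tested follicle cell genes were lower, as when adjusted over the list alone (camera adjusted p = 3.21e-55, and 0.0426 with an estimated correlation). The yolk protein genes Yp1, Yp2 and Yp3 were lower as well (log2 -6.22, -6.59 and -5.04). As 1 RPKM was added before logarithms, log2 changes of genes this close to 0 in eggs, Cp18 included, depend on that added value. The mRNA of yl, whose receptor takes up yolk, was at 712 ± 21.6 RPKM in oocytes and 755 ± 186 RPKM in eggs (SD, n = 2; limma adjusted p = 0.942).

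Of 6622 genes 230 passed, 28 higher and 202 lower. Whether loss of follicle cells lowered genes outside the follicle cell and yolk lists was not tested. Apart from follicle cell and yolk genes, the translation repressor gene Thor fell from 77.5 ± 17.4 to 12.1 ± 8.41 RPKM (SD, n = 2; log2 -2.74 ± 0.42 SE, adjusted p = 0.00217), Sip1 from 54.5 ± 3.9 to 15.9 ± 10.1 RPKM, and the peptidase gene Dip-B from 490 ± 43.1 to 138 ± 29.5 RPKM. Among rises, RNaseMRP:RNA, the RNA part of a processing enzyme, went from 13.2 ± 14.5 to 309 ± 255 RPKM, the splicing factor gene SF1 from 53.7 ± 1.39 to 135 ± 5.1 RPKM, the splicing regulator tra2 from 9.86 to 33.4 RPKM and the heterochromatin gene HP1b from 71.7 to 199 RPKM. The count of calls was decided by single libraries: without egg replicate 2 it was 1880. The calls of Thor, Sip1, Dip-B, tra2, HP1b and SF1 were lost with either oocyte library left out, at adjusted p of 0.143 to 0.96, and that of RNaseMRP:RNA without oocyte replicate 2 (log2 3.36, adjusted p = 0.232), while the follicle cell and yolk genes kept theirs. Without the filter on low values Thor, Sip1, tra2, HP1b and RNaseMRP:RNA were not called (adjusted p = 0.0627, 0.153, 0.142, 0.151 and 0.107), and with the puromycin inputs added no gene was, follicle cell and yolk genes included. None of the 29 regulators passed, among them CycB (1380 ± 10.9 and 1280 ± 348 RPKM), smg (280 ± 1.97 and 201 ± 80.4 RPKM) and png (186 ± 23.8 and 193 ± 30.1 RPKM; SD, n = 2, limma adjusted p = 0.868, 0.455 and 0.946), though 12 of the 29, smg (log2 -0.95) among them, passed without egg replicate 2, and cort also without egg replicate 1. No member of the other lists passed either, besides 1 early zygotic gene adjusted over its list alone. The cytosolic ribosomal protein mRNAs had a median log2 change of 0.49, with a camera adjusted p = 2.71e-10 that was 0.884 with an estimated correlation. Across genes, which are not independent replicates, the change correlated with transcript length (Spearman -0.227), and the difference between the 2 egg inputs did so more closely (-0.372).

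RNA of the footprint series gave a second set of mRNA levels. The follicle cell mRNAs Cp15 and Cp16 had 4181 and 99.91 RPKM in oocytes against 8.065 and 0.845 RPKM in eggs without cycloheximide, and 7628 and 288.3 RPKM against 7.443 and 0.4477 RPKM with it. Of 5840 genes 23 passed, 4 higher and 19 lower, and 641 had an unadjusted p under 0.05. The count was 8 without either egg library, 12 without either png egg library, and 46 and 35 without the oocyte libraries without and with cycloheximide.

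Whether polysomal mRNAs were held there by elongating ribosomes was tested with puromycin. In oocytes it lowered the medium and heavy share of cathD, a lysosomal protease gene, from 76.4% ± 6.71 (SD, n = 2) to 12.5% (log2 odds -4.53 ± 0.44 SE, adjusted p = 0.00117), of the thiolase gene yip2 from 57.4% ± 5.99 to 6.02%, and of the mitochondrial dehydrogenase gene scu from 51.5% ± 0.817 to 5.9%. Genes of the proteasome, which degrades proteins in meiosis and after, fell with them: Rpn6 from 74.1% to 21.5% and Pros26.4 from 62.0% to 14.6%. The mRNAs of mtrm (72.4% to 27.2%), dhd (67.3% to 21.8%), the mitotic kinase gene cdc2 (53.7% to 15.2%), RPA2 (50.7% to 14.4%), tral (64.5% to 29.4%), cup (53.6% to 24.0%) and me31B (50.2% to 25.7%) fell as well, the last 3 without passing once each fraction was scaled to its own total (log2 odds -0.57, -0.31 and -0.24). By contrast wisp stood at 39.8% ± 2.05 and 41.0%, osk at 46.3% ± 3.21 and 46.8%, and hb at 40.0% ± 0.00765 and 42.5% (SD, n = 2; limma adjusted p = 0.792, 0.926 and 0.575). With that scaling these 3 were called higher, at log2 odds of 1.41, 1.52 and 1.59.

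In oocytes 2546 genes passed, 28 higher and 2518 lower, with a median of -0.70; without oocyte replicate 1 the count was 1617. Scaling each fraction to its own total moved the median to 0.76 and turned the balance to 2587 higher and 476 lower, and 460 of the genes called lower became higher. Centred gradients gave a median of 0.00 with 716 higher and 1028 lower, and with heavy polysomes alone 870 passed. All 28 higher genes stayed higher under both scalings, which moved the median up and so favour keeping higher calls. Among them were the ribosomal protein genes RpS29 (6.4% to 16.8%) and RpL28 (9.1% to 20.2%), the latter lost without oocyte replicate 2 (log2 odds 1.04). Of 31 proteasome genes 30 were lower (31 adjusted over the list alone), 27 and 29 under the other scalings, and the list's median lay 1.85 below that of all genes (camera adjusted p = 2.56e-08, and 0.719 with an estimated correlation). Of 63 respiratory chain genes 48 were lower and of 35 DNA replication genes 33 (51 and 33 adjusted over the list alone), with 29 and 8 lower when each fraction was scaled to its own total. Of 83 cytosolic ribosomal protein genes 12 were lower and 3 higher (2 and 1 adjusted over the list alone), which turned to 38 higher and 1 lower with that scaling; RpL38 fell from 35.1% to 4.58%, though not in heavy polysomes alone (log2 odds -0.70). Of the 29 regulators 14 were lower, 0 higher and 15 not called.

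As deposited, puromycin lowered the polysomal share of most mRNAs in eggs, a balance that other scalings did not keep. The share of cdc2 fell from 78.1% ± 2.2 (SD, n = 2) to 7.72% (log2 odds -5.40 ± 0.28 SE, adjusted p = 3.74e-05), that of eIF4AIII from 79.2% to 8.31%, of the signalling adaptor gene 14-3-3zeta from 73.0% to 6.78%, of key from 79.0% to 9.07% and of the ubiquitin ligase gene CHIP from 80.2% to 10.1%. CycA fell from 64.6% ± 5.47 to 10.4% (SD, n = 2), CycB from 52.2% to 11.2%, fzy from 74.1% to 12.2% and tor from 54.4% to 11.0%. The median gene stood at 9.1% in the puromycin gradient of eggs, near the level that these mRNAs reached. The size of such falls therefore mostly reflects the share before treatment and does not rank mRNAs by their response to puromycin. This limit also applies to the gene lists in eggs below. The mRNA of wisp, which lost polysomes at activation, rose from 8.81% ± 0.489 to 19.9% (SD, n = 2; log2 odds 1.36 ± 0.20 SE, adjusted p = 0.000749), as did spri (8.74% to 16.7%) and enc (11.0% to 18.3%), but not in heavy polysomes alone (log2 odds 0.18, 0.61 and 0.34). The mRNAs of cort (10.4% and 10.7%), nos (5.43% and 6.02%) and osk (20.9% and 21.7%) were not called, and were called higher under either other scaling.

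In eggs 4128 genes passed, 51 higher and 4077 lower, with a median of -1.83. With each fraction scaled to its own total 1613 were higher and 1592 lower at a median of 0.03, and with centred gradients 1755 and 1539 at a median of 0.07; 1592 and 1539 of the 4077 stayed lower, and 686 and 795 turned higher. Of the 29 regulators 1 was higher, 20 were lower and 8 not called. Of 31 proteasome genes 30 were lower, 25 and 20 under the other scalings, Pros25 from 66.6% to 6.66%. Of 35 DNA replication genes 27 were lower and 2 higher (28 and 2 adjusted over the list alone), 14 and 12 with each fraction scaled to its own total, and RfC38 fell from 59.7% to 6.1%. Of 83 cytosolic ribosomal protein mRNAs 8 were lower (4 adjusted over the list alone) and 0 higher; the list's median was 7.3% ± 0.2 (SD, n = 2) before treatment and 6.8% after it. Their median change stood 1.71 above that of all genes (camera adjusted p = 4.04e-27, and 0.203 with an estimated correlation), and 62 and 78 of them were higher under the other scalings.

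**Figure D2:**
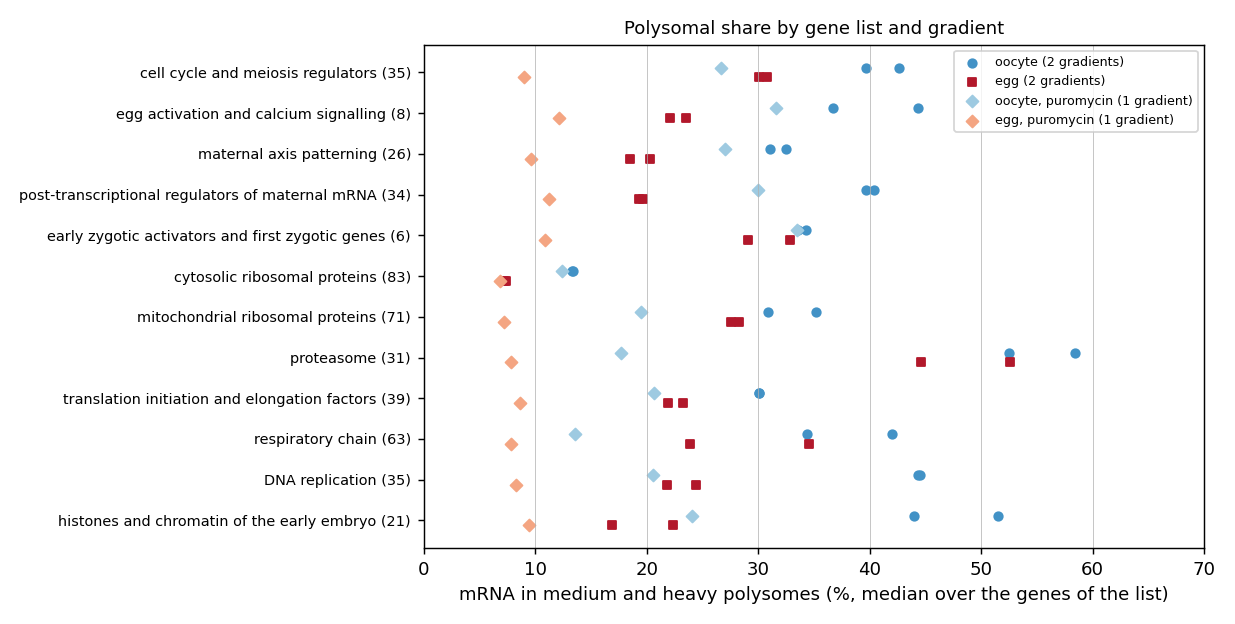
Points give the share (%) of mRNA in medium and heavy polysomes, as the median over the genes of each list, in 2 oocyte gradients, 2 egg gradients and 1 puromycin gradient per stage; numbers in parentheses are genes. The proteasome list fell from 58.4% and 52.5% in oocytes to 17.7% with puromycin, while cytosolic ribosomal proteins, at 7.2% and 7.4% in eggs, stood at 6.8% with puromycin as deposited, and 62 of 83 were higher with each fraction scaled to its own total.

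Translational efficiency from ribosome footprints gave an independent measure of activation. The repressor gene smg rose from a log2 efficiency of -3.66 ± 1.79 in oocytes to 2.45 ± 0.12 in eggs (SD, n = 2; difference 6.10 ± 0.68 SE, adjusted p = 4.51e-05). CycA rose from -2.64 ± 1.06 to 3.41 ± 0.03 (SD, n = 2; difference 6.05 ± 0.43 SE, adjusted p = 3.84e-06), and the Toll receptor gene Tl from -1.36 ± 0.21 to 4.43 ± 0.24 (SD, n = 2). The kinase gene nmo, the Notch ligand gene Delta and the DNA-binding protein gene retn rose by 5.50, 5.50 and 5.49. Among falls, the exonuclease gene WRNexo changed by -5.92, Men by -5.50, Gapdh2 from 1.61 ± 0.15 to -3.88 ± 0.27 (SD, n = 2; difference -5.49 ± 0.17 SE, adjusted p = 8.47e-07), and the DNA polymerase gene PolD1 by -4.90. The meiotic genes mtrm and dhd changed by -4.46 and -4.48.

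Of 5840 genes 4131 passed with limma, 2686 higher and 1445 lower, at a median log2 difference of 0.50. RPKM values do not show a change shared by all mRNAs. With libraries centred on their median the median was -0.27, with 1883 genes higher and 2565 lower. All 1445 lower genes were also lower then, and 1883 of the 2686 higher genes were higher. Centring moved the differences down, which favours keeping lower calls. Of 28 regulators in the table (tor had no entry) 16 were higher, 9 lower and 3 not called. CycB rose by 3.93, CycB3 by 3.05, the phosphatase genes stg by 3.47 and twe by 0.90, polo by 1.53, the calcineurin regulator sra by 3.85, and the translation repressor genes brat by 4.88 and pum by 1.83. Among patterning genes bcd rose by 3.91, hb by 3.23, cad by 2.54, and zld, which activates the zygotic genome, by 5.15. The gene fzy rose by 0.89. The pum and twe calls were lost without the egg library with cycloheximide (1.42 and 0.67, adjusted p = 0.0845 and 0.0957), that of fzy without either egg library (0.94 and 0.84, adjusted p = 0.0672 and 0.0958), and those of fzy and twe also with centred libraries (0.12 and 0.12).

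The 9 lower regulators were png (-1.53), gnu (-3.28), cort (-3.60), wisp (-1.60), osk (-2.19), me31B (-2.04), cup (-2.17), tral (-1.46) and dhd. The png call was lost without the egg library with cycloheximide (-1.37, adjusted p = 0.0657). The 3 not called were plu (-0.56), nos, listed as nanos (0.84), and BigH1 (-0.23). Without the oocyte library with cycloheximide all 3 passed, at -0.94, 1.48 and -0.53, and with centred libraries plu (-1.33) and BigH1 (-1.01) did. With the ratio of footprints to RNA tested per sample, an alternative chosen after the data were seen, plu and nanos passed (adjusted p = 0.0499 and 0.044).

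Lists gave 2 directions. Of 7 early zygotic genes 5 were higher and 0 lower (camera adjusted p = 0.0326, and 0.705 with an estimated correlation), 5 and 1 with centred libraries, including Clamp (3.84) and slam (3.54), and their median lay 3.04 above that of all genes. Of 26 axis genes 14 were higher and 6 lower. Of 84 cytosolic ribosomal protein genes 55 were lower and 4 higher, the same adjusted over the list alone (camera adjusted p = 3.79e-10, and 0.705 with an estimated correlation). Lower genes also outnumbered higher ones among 36 DNA replication genes (21 and 7, Fen1 by -4.37 and RPA1 by -2.94), 31 proteasome genes (14 and 0), 72 mitochondrial ribosomal protein genes (29 and 3), 66 respiratory chain genes (27 and 3), 21 histone and chromatin genes (8 and 5) and 10 activation genes (5 and 3). Adjusted over the list alone the DNA replication, proteasome, mitochondrial and respiratory lists had 22 and 7, 13 and 0, 26 and 3, and 26 and 3. All of these lists kept that direction with centred libraries. As centring moved the differences down, it favoured this outcome for the lists with more lower genes, so it is no check of them. The cell cycle (17 higher and 10 lower of 35, CycD by 4.62), post-transcriptional (18 and 11 of 36, sqd by 4.62) and translation factor lists (18 and 6 of 41) turned to 10 and 14, 14 and 16, and 3 and 16 with centred libraries. Cycloheximide itself changed 0 genes at the limma threshold, while 156 had an unadjusted p under 0.05. That test fits a shift shared by all stages, so an effect in oocytes alone would go into the spread. Median log2 efficiencies without and with it were -0.39 and -0.89 in oocytes, 0.03 and 0.09 in eggs, and -0.36 and -0.35 in png eggs.

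Polysomal share and translational efficiency were compared over 4853 genes measured in both. The changes at activation correlated across genes, which are not independent replicates, with Spearman 0.645 and Pearson 0.65. Of 901 genes with a higher polysomal share 777 had a higher efficiency (Fisher's exact test, odds ratio 10.1, p = 3.14e-161; 424.4 from independent lists) and 1 a lower one. Of 2471 genes with a lower polysomal share 1056 had a lower efficiency (odds ratio 18.4; 585.0 from independent lists) and 679 a higher one. In that last group were hb, pum, bcd and zld, whose polysomal share fell while their footprints per mRNA rose. The fall was lost with either other scaling for bcd (log2 odds -0.66 and -0.61) and with centred gradients for zld (-0.38), so their opposite directions rest on the scaling as deposited, and the rise of pum was lost without the egg library with cycloheximide (1.42). The count of 679 depends on scaling too. Over all genes tested the median change was -0.60 for the polysomal share as deposited and 0.50 for efficiency. With centring these medians were -0.09 and -0.27. How many of the 679 genes kept opposite calls then was not counted. The gene smg was called by footprints alone.

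**Figure D3:**
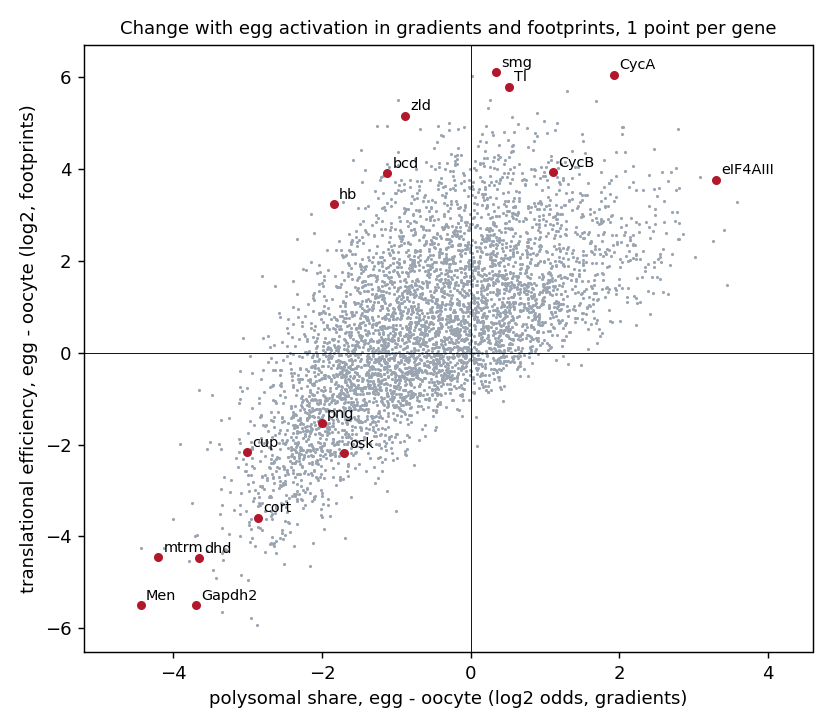
Each of 4853 points is a gene, with the change from oocyte to egg in polysomal share (log2 odds, x axis) and in translational efficiency (log2, y axis). The Spearman correlation was 0.645, with CycA at 1.93 and 6.05 and Men at -4.44 and -5.50.

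The part that PAN GU kinase plays was tested in eggs of png mutant mothers. RNA of png itself was present in all libraries: 113 and 114 RPKM in oocytes, 101 and 102 RPKM in eggs, and 92.1 and 96.9 RPKM in png eggs, without and with cycloheximide. The RNA level of png therefore did not tell the mutant libraries from the others. Footprints on png were at 18.1 and 10.3 RPKM in eggs and at 173 and 189 RPKM in png eggs.

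In png eggs smg fell from a log2 efficiency of 2.45 ± 0.12 in eggs to -5.91 ± 0.07 (SD, n = 2; difference -8.36 ± 0.68 SE, adjusted p = 5.82e-06). CycA fell from 3.41 ± 0.03 to -2.58 ± 0.11 (SD, n = 2; difference -5.99 ± 0.43 SE, adjusted p = 2.83e-06), and did not pass between png eggs and oocytes (0.06, adjusted p = 0.91). The histone demethylase gene Kdm4A changed by -6.94, Delta by -6.93, the decapping enzyme gene DCP2 by -6.91, the signalling genes tub and cact by -6.37 and -3.93, the deadenylase gene twin by -5.73 and CycB by -5.13. Rises were those of the amino acid transporter gene path (6.75), WRNexo (6.27), the mismatch repair gene Msh6 (6.01), PolD1 (5.94), and the meiotic genes mtrm (5.78), nod (5.21), dhd (4.71) and endos (4.04). The efficiency of Gapdh2 rose from -3.88 ± 0.27 to 2.12 ± 0.03 (SD, n = 2), and that of dhd did not pass between png eggs and oocytes (0.23, adjusted p = 0.386).

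Of 5840 genes 4094 passed, 1876 higher and 2218 lower in png eggs, at a median of -0.11. Centred libraries gave a median of 0.43 with 2762 higher and 1823 lower, and the 1876 and 1823 genes were in the same direction in both. Here centring moved the differences up, which favours keeping higher calls. Of 28 regulators 10 were higher, 14 lower and 4 not called. Lower beside those above were Tl (-4.70), stg (-4.51), sra (-4.27), brat (-3.16), hb (-2.76), cad (-2.17), CycB3 (-1.85), zld (-1.62), bcd (-1.51), nanos (-1.46) and osk (-0.61). Higher beside dhd were png (3.74), tral (2.82), cort (2.75), cup (2.11), gnu (0.99), twe (0.84), BigH1 (0.66), wisp (0.65) and polo (0.61). The calls of zld and CycB3 were lost without the egg library with cycloheximide (-1.15 and -1.56, adjusted p = 0.0714 and 0.0805). The calls of osk, BigH1, wisp and polo were lost without any 1 of the 4 egg and png egg libraries, at -0.75 to -0.47, 0.51 to 0.81, 0.50 to 0.80 and 0.54 to 0.68. That of gnu was lost without either egg library (0.82 and 1.15) or the png egg library with cycloheximide (0.68). Those of twe (0.62, 0.76 and 0.92) and nanos (-0.98, -1.62 and -1.30) were lost without the egg library without cycloheximide or either png egg library, and osk (-0.07) and nanos (-0.92) also with centred libraries. Not called were plu (0.93), fzy (-0.54), pum (-0.47) and me31B (-0.31), of which the first 3 passed without either oocyte library, at the same log2 differences, and plu with centred libraries (1.47). With the ratio tested per sample plu and fzy passed and osk and wisp did not (adjusted p = 0.00256, 0.0353, 0.0906 and 0.0721).

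Gene lists were compared between png eggs and eggs, which shares the egg libraries with the comparison at activation, so opposite directions of the comparisons also arise with no effect. Of 36 DNA replication genes 27 were higher in png eggs and 6 lower (camera adjusted p = 1.64e-05, and 0.898 with an estimated correlation), Fen1 by 5.04 and RPA1 by 4.26, with a list median 1.88 above that of all genes. Higher genes also outnumbered lower ones among 31 proteasome genes (18 and 1), 66 respiratory chain genes (29 and 1), 84 cytosolic (26 and 7) and 72 mitochondrial ribosomal protein genes (21 and 11), 21 histone and chromatin genes (14 and 3) and 10 activation genes (6 and 1). Lower genes outnumbered higher ones among 26 axis genes (17 and 8) and 7 early zygotic genes (5 and 1). Adjusted over the list alone the respiratory, cytosolic and mitochondrial lists had 25 and 1, 19 and 7, and 16 and 9. These directions held with centred libraries. As centring moved the differences up, it favoured this outcome for the lists with more higher genes, so it is no check of them. The cell cycle, post-transcriptional and translation factor lists, with 13 and 13, 14 and 14, and 10 and 9 higher and lower, had 18 and 13, 18 and 12, and 23 and 7 with centred libraries.

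**Figure D4:**
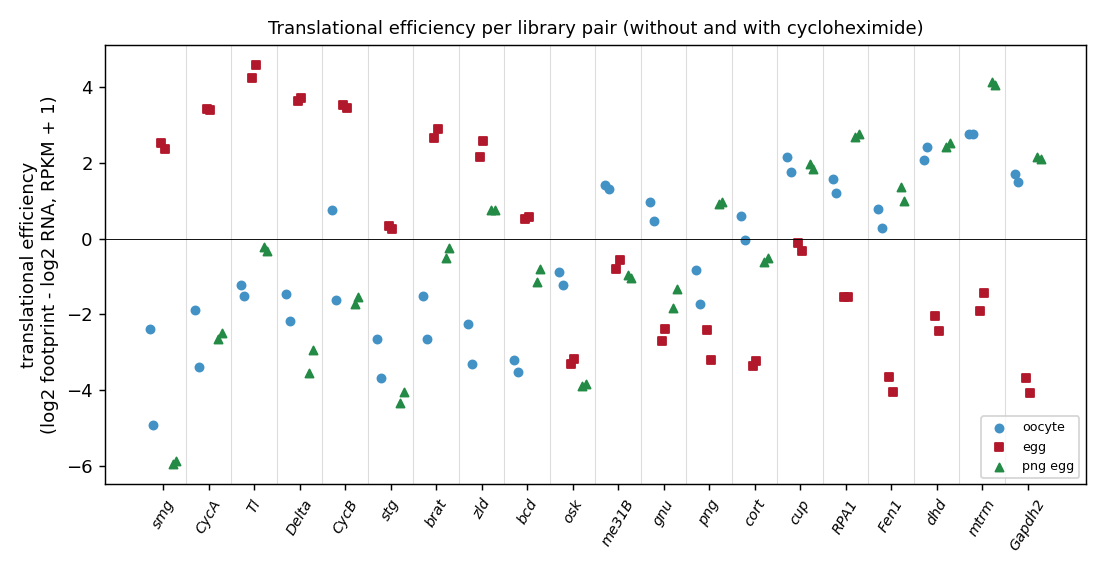
Points give the log2 translational efficiency (footprint minus RNA, RPKM + 1) of 20 named genes in oocytes, eggs and png eggs, 1 point without and 1 with cycloheximide each. The gene smg had a mean of -3.66 in oocytes, 2.45 in eggs and -5.91 in png eggs, and Gapdh2 1.61, -3.88 and 2.12.

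How many activation changes had an opposite difference between png eggs and eggs was counted over 5840 genes. Of the 2686 genes higher at activation 1786 (66.5%) were lower in png eggs than in eggs, 247 were higher and 653 not called. Of the 1445 genes lower at activation 1095 (75.8%) were higher in png eggs, 45 lower and 305 not called. Fisher's exact test gave odds ratios of 12.5 (95% interval 11 to 14.3) and 14.5 (12.5 to 16.7). Both comparisons share the egg libraries, which alone gave a correlation of -0.5 in simulated data, against -0.751 observed. Independent lists would share 1020.1 and 464.2 genes. The covariance was -2.728 against -0.0396 simulated, and correlations that share no egg library were -0.743 and -0.721. As variation between biological samples was not measured, a deviation shared by the egg libraries of both cycloheximide states would also give negative values here. Against oocytes 1191 of the 2686 genes (44.3%) were still higher in png eggs, 603 were lower and 892 not called. Of the 1445 genes 406 (28.1%) were still lower, 397 were higher and 642 not called. A gene lower in png eggs than in eggs can still lie above oocytes, as zld did, so these counts overlap with those above. Among genes still higher were zld (3.54), bcd (2.40), retn (3.96) and Clamp (3.61), and still lower were osk (-2.81), me31B (-2.35) and gnu (-2.29). Between png eggs and oocytes 3465 genes passed, 2105 higher and 1360 lower, with 2130 and 2201 without the png egg library without and with cycloheximide, and 1959 higher and 1949 lower with centred libraries.

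RNA levels of png eggs and eggs differed for 359 of 5840 genes, 252 higher and 107 lower. That count is not stable: it was 3 without either egg library, 8 without either png egg library, and 1749 and 1756 without the oocyte libraries without and with cycloheximide. Of 84 cytosolic ribosomal protein genes 18 were lower and 0 higher, and 59 were lower adjusted over the list alone (camera adjusted p = 1.09e-28, and 0.534 with an estimated correlation), with a list median 0.56 below that of all genes. With centred libraries 882 genes passed, 411 higher and 471 lower, and 40 of the ribosomal protein genes were lower.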

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

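The interaction between stage and puromycin and the tests of mixed egg footprints, a wrong label, follicle genes listed in the gradient and the scaling of fractions were chosen after results had been seen; those of mixed egg footprints and of a wrong label replaced earlier tests of the same explanations.

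As deposited, puromycin lowered the polysomal share more in eggs than in oocytes, which was noticed because the effect of the same treatment differed between the stages in a direct test. With limma 2835 of 5088 genes passed for the interaction, 2538 lower and 297 higher in eggs, at a median of -0.99. Each stage had 1 puromycin gradient, and centred gradients, which bring the median near 0 by construction, gave 1368 higher and 934 lower. The scaling of fractions to the spike-in cannot be told apart: with each fraction scaled to its own total the median was -0.55, with 371 higher and 1843 lower, so the stage difference kept its direction, but the median effect itself was then 0.76 in oocytes and 0.03 in eggs. The length of the mRNA was argued against as the whole cause, as the shortest group by coding length had a median of -0.97 and the longest -0.65, and whether ribosomes in eggs elongate faster was not tested.

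The input of puromycin-treated eggs held follicle cell mRNAs that the other egg inputs lacked, in a library outside the main comparisons. Over the 20 genes of the list the median was 8.33 RPKM, against 0.0 RPKM in both egg inputs, 60.6 and 54.7 RPKM in oocytes and 15.9 RPKM in puromycin-treated oocytes. Cp15 alone stood at 26830 RPKM.

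For that library 3 explanations were weighed. The difference from the other egg inputs followed transcript length with a Spearman correlation of -0.509 across genes, which fits a length bias for the difference across genes, though the 2 egg inputs differed from each other by -0.372. The sign was the other way in the input of puromycin-treated oocytes (0.647) and in the fraction sum of the same puromycin-treated eggs (0.523). It does not account for the follicle cell mRNAs, as medians by length ran from -0.15 for the shortest mRNAs to -1.94 for the longest. Genes higher in eggs lay at a median position of 0.44 between oocyte (0) and egg (1), with quartiles of 0.02 and 0.87, and those lower in eggs at 0.19 (quartiles -0.13 and 0.44), so an oocyte library under the wrong label cannot be told apart. Another cell type in the lysate cannot be told apart either: the fraction sums of its gradient correlated with those of the egg gradients at 0.76 or more, against 0.973 between those, but only 1 of the 18 follicle genes above 1 RPKM in the input was listed in the gradient, against 13 of 15 in puromycin-treated oocytes. The input correlated with the fraction sum of its own gradient at 0.665, against 0.975 and 0.929 for the other egg gradients. Both go against another cell type in the lysate, but neither decides it. Genes were listed only with a heavy-polysome value of at least 4. Heavy polysomes held 2.6% of the mRNA here against 10.5% in puromycin-treated oocytes, so the cutoff alone can leave genes out. The opposite length trends of this input and its fraction sum can lower 0.665. That explanation also stays open because 1 gene was listed, and because a length trend that both puromycin gradients had can by itself lower the correlation of 0.76. No biological explanation was tested.

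The oocyte footprint libraries without and with cycloheximide differed more than those of eggs, with median log2 efficiencies of -0.39 and -0.89 against 0.03 and 0.09. Footprints of eggs mixed into the library without cycloheximide were argued against by a Spearman correlation of 0.034 across genes with the change at activation. The follicle cell genes Cp15 and Cp16 and the yolk list gene yl together held 3.55% and 10.31% of the summed footprint RPKM in oocytes. Most of this was Cp15, at 25200 and 71100 RPKM, while yl had 870 and 517.8 RPKM. Footprints of follicle cells cannot be told apart: with these 3 genes left out the spread between the oocyte libraries was 1.71 times that of eggs. A biological effect of cycloheximide in oocytes was not tested, since each library stands alone.

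Cycloheximide itself gave 0 calls as the samples were grouped, and the highest other split of the 6 samples gave 1446. With 0 real calls all 10 splits have at least as many by construction, and 10 are too few to give a share under 0.05. The splits with that count put both egg samples with 1 oocyte sample and both png egg samples with the other. As the model has a term per stage, only the oocyte samples with and without cycloheximide then inform the contrast. Those calls therefore reflect the difference between the oocyte libraries.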

How the results depend on the processing

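Of 150 alternatives to counts and correlations 118 kept the value near that of the main analysis and 32 moved it, where for counts only the total was compared. The balance of higher and lower genes turned under some of the 118: with each fraction scaled to its own total puromycin in oocytes gave 2587 higher and 476 lower, against 28 and 2518, and with centred libraries efficiency of eggs against oocytes gave 1883 and 2565, against 2686 and 1445. Of 2531 alternatives for named genes 2368 kept direction and side of the threshold, 101 lost the call, 59 gained it and 3 reversed. The reversals were those of plu without egg replicate 1 (0.61, against -1.07 without egg replicate 2) and of polo (0.52) and cad (0.54) with each fraction scaled to its own total. The input count of 230 became 113 with a stricter filter and 0 with puromycin inputs added, and 167 to 1880 with single libraries left out. Puromycin in oocytes went from 2546 to 870 with heavy polysomes alone and to 1617 to 3152 with single gradients left out. The RNA of eggs against oocytes went from 23 to 35 without a cycloheximide term, 56 with a pseudocount of 5, 128 with centred libraries, 12 with only those stages fitted, and 8 to 46 with single libraries left out. That of png eggs against eggs went from 359 to 609, 882, 1750 and 3 to 1756 under the last 4 of these. Efficiency in png eggs against oocytes went from 3465 to 2130 to 3956. The drop of all mRNA in polysomes, -12.4 percentage points, was -19.3 with low polysomes and -7.8 with heavy polysomes alone. It was -8.5 with the follicle cell list left out and -8.3 over genes listed in every gradient, choices made after the data were seen. The genes left out thus carried part of the drop. Other mRNAs of follicle cells stayed in, and their part is unknown. Of 43 list results passing camera 1 passed with an estimated correlation. The cause was not tested. Read depth is unknown, so its limit on low values could not be stated.

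Replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.029 in gradients and -0.028 in inputs. With the replicate block 370 input genes passed against 230, and 3597 of the polysomal shares against 3683 without the block in the same 4 gradients. With the block 1 of the regulators named beforehand lost its polysomal call.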

Other observations

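The tests of ribosomal protein mRNAs against other mRNAs matched for coding length, and for coding length and polysomal share, were chosen after the result had been seen.

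As deposited, puromycin changed the polysomal share of cytosolic ribosomal protein mRNAs little, with median effects of -0.13 in oocytes and -0.12 in eggs over 83 genes. With each fraction scaled to its own total 38 were higher in oocytes and 62 in eggs. Their short coding sequences were argued against as the whole cause, since 1019 other genes of the same coding lengths had medians of -0.92 and -2.33. A small polysomal share before treatment cannot be told apart: over 73 other genes of the same coding lengths and a share of 5.47% to 11.41% in eggs the median effect in eggs was -0.14, with quartiles of -0.31 and 0.14, but such a share lies near the 9.1% of the median gene after puromycin, which leaves it little room to fall. Oocytes were not matched for share.

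In both oocyte gradients and neither egg gradient 458 genes were listed, of which 141 had an input mean under 1 RPKM in eggs, and 9 genes were listed the other way round.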
